A study of Mus musculus with 3 samples.

How the data were processed

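Total RNA was profiled in 3 snap-frozen tumours of the NDL(UCD) transplantable mouse mammary tumour line. Per the labels' protocols, the line was propagated in culture and its cells were injected into mammary fat pads of female FVB/NJ mice aged 6 to 8 weeks, and tumours were taken at a width of 5 to 10 mm. Ribosomal RNA was depleted by capture probes, and directional libraries were made from 50 ng of depleted RNA with random-hexamer priming and tagging of both cDNA ends, per the labels' protocols. Such libraries hold transcripts with and without poly(A) tails. Random priming and amplification can favour fragments of some base compositions. The tumours were numbered 1 to 3 in accession order, because the sample titles give no plain replicate number. The titles hold other numbers whose meaning is not given in the sources used here, so lanes or library batches cannot be excluded as a source of any difference between tumours.

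The authors' deposited values are FPKM per gene with a lower and an upper interval bound and a status, per the file headers. The submitters' processing notes name TopHat for alignment, Cufflinks for quantification and the mouse build mm9, without roles, so the roles given here are the usual ones of these tools. Tool versions, the annotation release and the strand setting are not given in the sources used here. FPKM divides fragments by transcript length and by library total, so a few very abundant transcripts lower all others, and an FPKM of a locus shorter than a fragment is set by few fragments. Coordinates are those of the files on mm9, written from 1.

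Each file held the same 22310 gene rows, which gave 21881 symbols after the rows of 221 repeated symbols were added up. Rows whose status was not OK in all 3 tumours were left out of the tests, which removed 182 symbols. The FPKM totals were 318509, 375968 and 364195 in tumours 1, 2 and 3. The half-width of each deposited interval was taken as 2 standard errors. The implied fragments, the squared ratio of FPKM to its standard error, came out within 0.02 of a whole number for 70.5%, 71.1% and 69.3% of rows with fewer than 60 fragments, and summed to 11.6, 12.4 and 13.3 M (1e6). From single-start genes with whole values, tumours 2 and 3 had 0.962 and 1.07 times the depth of tumour 1. At the median locus 1 FPKM corresponded to 69.2, 66.3 and 73.8 fragments, so that a count of 0, which allows 3 fragments, allows 0.0433, 0.0453 and 0.0406 FPKM. Intervals and such limits cover counting error only. Implied fragments were not whole for all rows and no count test was run.

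Levels were tested with limma 3.58.1 in R 4.3.3 on log2((FPKM + 0.1)/(1 + 0.1)) with an intercept-only model, a mean-variance trend and robust moderation, against 0. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called above or below 1 FPKM, a conventional level and not a biological boundary. The series design states separate mice, so the spread is between animals that carry the same line. Differences between tumours were tested per gene with Cochran's Q (2 degrees of freedom) on the deposited standard errors for genes with a mean of at least 1 FPKM, and a ratio of at least 2 was required. The 33 gene lists hold 436 entries, of which 5 genes were not found under any symbol used here and 1 had a status other than OK. Older symbols of the files were used for Vsir, Jchain, Adgre1 and Mzb1. The 27 fixed contrasts were tested by an exact two-sided sign-flip permutation test over tumours. List shifts between tumours were set against 10000 random lists in 20 expression bins, for members with a mean of at least 0.5 FPKM and lists of at least 3 such members. Lists, contrasts, main tests, most alternatives and the rule for named genes were fixed before the data were examined. The removal of GC and length trends, the omission of loci under 300 bp and the tests of the closing section were added afterwards.

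The named genes are those of the gene contrasts, the 3 highest and 2 lowest members of each list, the 10 genes with the highest mean and, per tumour, the 5 largest rises and falls against the other tumours among genes past the Q test. Other genes were chosen after their values were seen. These are Elf5, Kit, Prom1, Aqp5, Chi3l1, Apod, Expi, Ifit1, Adipoq, Zfp260, Mmp13, Ly6d, Cxcl14 and Ccl4, the neighbours of Erbb2, and the genes left out for their status. Some genes that the rule or this choice would name are not reported here.

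GC content and length of transcripts came from GENCODE vM21, used for sequence properties by gene name only and never for coordinates. They matched 19582 symbols directly and 1872 through a synonym, 98.0% in all. The GC and length trends of each tumour were removed by lowess with a span of 0.3, fitted on genes with a mean of at least 1 FPKM and a locus of at least 300 bp, after seeing the data. The removal assumes that no biological difference follows GC content.

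The level test, the Q test and the list shifts with removal of the trends were tested on simulated data. The contrasts, the permutation test over genes and the correlations were not. For the level test on 18028 genes, 60% and 48% of 50 genes placed 1 log2 unit above or below the level were called, 100% and 98% of 50 placed at 2 log2 units, and 0.6% of 2000 genes at the level. For the Q test on 10976 genes, all of 50 genes each changed 3-, 4- and 8-fold were called, with 0% of 50 genes changed 1.5-fold and 0% of 10776 unchanged genes. Those changed 1.5-fold passed Q in 92% of cases but stayed under the required ratio of 2. The simulated spread was counting error only, which is the error that Q assumes, so a low rate of false calls was built in. For list shifts with a simulated GC trend on 17715 genes, 37.5% of 40 lists raised by 0.6 log2 units were found before removal of the trends and 100% after, with 10% of 40 unchanged lists outside the central 95% before removal and 5% after. The simulated lists were randomly drawn genes, so these rates do not cover lists of related genes. The simulated trend was also steeper than that between tumours 1 and 3 (Spearman rho -0.91 against -0.70). Its noise was a set value below the spread of the data, and many fixed lists have fewer members. The 100% may therefore overstate how often such a shift would be found in the data. Alternatives covered pseudocounts, filters, scalings, levels, summaries over members and leaving out each tumour. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.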

Results

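Gene expression was measured by total RNA sequencing in 3 tumours grown from NDL(UCD), a transplantable mouse mammary tumour line of an ErbB2 model, each in a different female FVB/NJ mouse. The NDL model is known to carry an activated Erbb2 (Neu) transgene expressed from a mammary tumour virus promoter. The series describes the 3 tumours as biological replicates of 1 line, and they form a single group with no untreated, normal or other tumour group beside it. The comparisons below are therefore between genes within the tumours, between each gene and a fixed level of 1 FPKM, and between the 3 tumours themselves. Values are in FPKM, fragments scaled by transcript length and library total, given as mean ± SD over n = 3 tumours unless a single tumour is named. The deposited intervals corresponded to 11.6, 12.4 and 13.3 M (1e6) fragments in tumours 1, 2 and 3. Of 18028 gene symbols listed above 0 in at least 1 tumour, 9778 were above 1 FPKM and 5864 below it by limma with a Benjamini-Hochberg adjusted p under 0.05, while 2386 were not separated from that level and a further 3671 symbols were listed at 0 in all 3 tumours. The calls above made up 62.5% of all calls. Rescaling each tumour to the same FPKM total of 1000000 raised the median gene by 1.46 log2 units and gave 11636 calls above and 4208 below, 73.4% above.

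Transferrin (Trf), an iron-binding protein secreted by mammary epithelium, was the most abundant transcript whose locus was at least 300 bp long, at 8699.8 ± 3438.6 FPKM (mm9 chromosome 9, 103111206 to 103132616). Other secreted epithelial products were also high. Among them were Csn3, which encodes kappa-casein (2561 ± 602 FPKM), and Lcn2, the siderophore-binding lipocalin 2 (2528 ± 450.3 FPKM). Apod, Chi3l1 and Expi, named here after their values were seen, reached 2739 ± 471, 2383 ± 1066 and 1785 ± 425 FPKM. The 10 highest symbols overall also held the RNA components of 2 ribonucleases, Rmrp at 7202 ± 3007 FPKM and Rpph1 at 5246 ± 1925 FPKM, and the mitochondrial-like locus Mtrnr2l at 3522 ± 1466 FPKM. The other 6 were the small RNA loci Snord93, Mir3064, Snord22, Snord57, Rnu12 and Mir682. Snord93 (31671 ± 10824 FPKM), 45 bp long, rested on only 19, 9 and 15 implied fragments, and loci under 300 bp had a median of 4. Such loci held 35.0%, 30.6% and 26.1% of all FPKM in tumours 1, 2 and 3.

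Erbb2, the receptor tyrosine kinase after which the model is named, lay at 195 ± 5.07 FPKM, with deposited values of 199.9, 195 and 189.7 FPKM in tumours 1, 2 and 3 (mm9 chromosome 11, 98273798 to 98299030; limma adjusted p = 1.1e-07 against 1 FPKM). With the GC and length trends described below removed, the values were 260.8, 182 and 156 FPKM, so the near equality holds for the deposited values only. Its dimerisation partner Erbb3 reached 22.5 ± 1.95 FPKM and Egfr 10.1 ± 0.991 FPKM. Erbb4 was listed at 0 in tumours 1 and 3 and at 0.00871 FPKM in tumour 2, and Erbb2 exceeded it by 10.89 ± 0.08 log2 units (10.62 ± 0.67 with the trends removed). On the log2(FPKM + 0.1) scale Erbb2 exceeded Erbb3 by 3.11 ± 0.15 and Egfr by 4.26 ± 0.18 (SD, n = 3), which are folds of 8.64 and 19.1. With the trends removed the SDs grew, to 3.11 ± 0.27 for Erbb3 and 4.25 ± 0.88 for Egfr, where the fold went from 37.6 in tumour 1 to 11.5 in tumour 3. Of 18 measured ErbB receptors, ligands and adaptors, 11 were above 1 FPKM and 5 below. The adaptor Shc1 was at 15.9 ± 5.00 FPKM, whereas the ligand Nrg3 was listed at 0 in all 3 tumours. FPKM per symbol does not separate a transgene from the endogenous gene, and whether all transgene fragments aligned to mm9 was not examined.

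The genes next to Erbb2 on mm9 chromosome 11 were far lower than Erbb2. Within 100 kb lay 9 other genes, of which 8 were under 19.5 FPKM, 10% of the Erbb2 mean. Grb7, which encodes an adaptor and starts 9118 bp downstream, was at 3.19 ± 1.00 FPKM, and Erbb2 exceeded it by 5.94 ± 0.43 log2 units (61.2-fold). Stard3, a lipid transfer gene upstream, was at 15.05 ± 3.53 FPKM. The exception was 1810046J19Rik, whose annotated locus overlaps the end of Erbb2 by 9 bp, at 49.9 ± 13.7 FPKM. Whether fragments were assigned by strand is not given in the sources used here, so values of overlapping genes are uncertain.

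**Figure D1:**
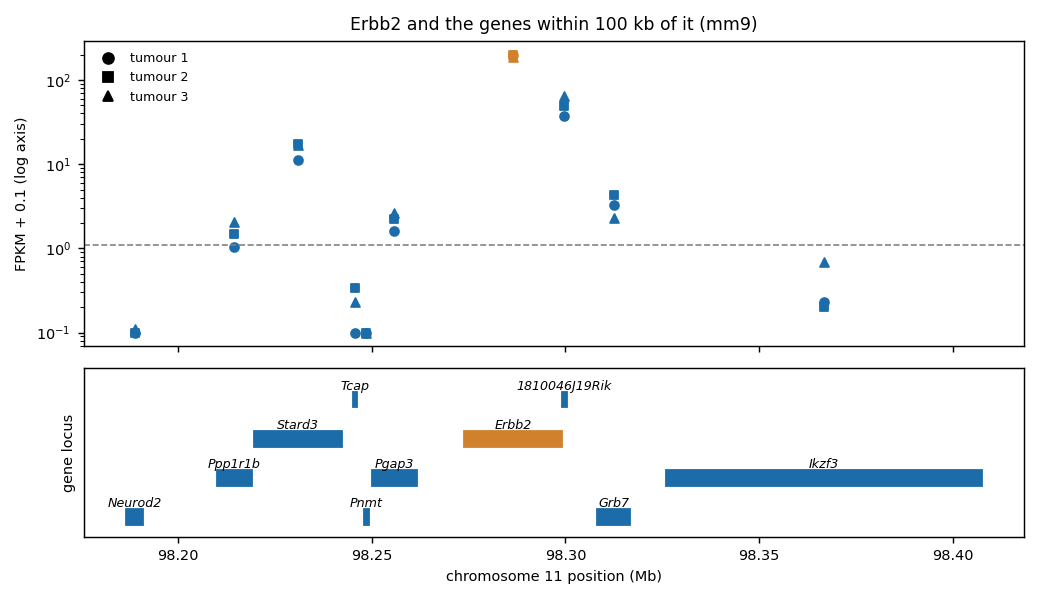
Erbb2 and the 9 genes within 100 kb on mm9 chromosome 11. The upper panel shows FPKM + 0.1 on a log axis in each tumour, with Erbb2 in orange and a dashed line at 1 FPKM, and the lower panel shows each locus to scale in Mb. The 3 deposited Erbb2 values lie between 189.7 and 199.9 FPKM, above every neighbour.

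Steroid hormone receptors and their targets were low. The oestrogen receptor gene Esr1 was at 3.04 ± 0.785 FPKM and the progesterone receptor gene Pgr, a classical oestrogen target, at 0.0918 ± 0.0293 FPKM. Of 10 measured genes of this group 2 were above 1 FPKM and 6 below. The prolactin receptor gene Prlr was the highest at 6.53 ± 5.23 FPKM, with 12.6 FPKM in tumour 1 against 3.74 and 3.28 FPKM in the others as deposited, but 6.51, 4.57 and 5.16 FPKM with GC and length trends removed. The calcitonin receptor gene Calcr was at 0.0253 ± 0.0348 FPKM. Erbb2 exceeded Esr1 by 5.99 ± 0.31 log2 units, and Esr1 exceeded Pgr by 4.02 ± 0.19.

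Luminal epithelial genes were among the highest of all cell type lists. The simple-epithelium keratins Krt18 and Krt8 lay at 526 ± 143 and 147 ± 47.0 FPKM, the adhesion molecule Epcam at 202 ± 3.74 FPKM and the surface protein Cd24a at 159.8 ± 46.9 FPKM, and 16 of 19 measured members were above 1 FPKM. With GC and length trends removed Epcam was at 276, 184 and 161 FPKM in tumours 1, 2 and 3. Basal keratins were low: Krt5 was at 0.0690 ± 0.0711 FPKM and Krt6b at 0.00933 ± 0.0117 FPKM. Of 14 measured basal and myoepithelial genes 2 were above 1 FPKM and 8 below, the 2 being the regulator Id4 (4.98 ± 2.13 FPKM) and Krt14. Only 1 was above without tumour 2 or with median-of-ratios scaling. Krt14 differed between tumours, at 2.80, 10.4 and 1.07 FPKM. Per tumour, the luminal list mean exceeded the basal list mean by 5.42 ± 0.20 log2 units (SD, n = 3), Krt8 exceeded Krt5 by 9.78 ± 0.39 and Krt18 exceeded Krt14 by 7.28 ± 1.52. Within the luminal list Foxa1, a transcription factor of hormone-sensing luminal cells, was at 0.0373 ± 0.0286 FPKM, Spdef was not separated from 1 FPKM at 0.733 ± 0.204 FPKM, and Krt19 was listed at 0.261, 0.0302 and 4.01 FPKM. Elf5, Kit and Prom1, known from luminal progenitor and alveolar cells and named here after their values were seen, were at 55.3 ± 3.49, 29.5 ± 3.15 and 26.1 ± 10.1 FPKM.

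Mesenchymal genes were split. The intermediate filament gene Vim was at 114 ± 28.1 FPKM and the epithelial cadherin gene Cdh1 at 42.1 ± 4.32 FPKM. Cdh1 minus Vim was -1.41 ± 0.23 log2 units, negative in 3 of 3 tumours. The mesenchymal cadherin Cdh2 was below 1 FPKM at 0.486 ± 0.0985 FPKM, and Cdh1 exceeded it by 6.18 ± 0.38 log2 units. Of 11 measured genes of mesenchymal transition 5 were above 1 FPKM and 5 below, and the luminal list mean exceeded theirs by 3.55 ± 0.10 log2 units. Without tumour 2 the count above was 3. Fn1 (30.9 ± 11.6 FPKM) and Twist1 (6.42 ± 0.663 FPKM) followed Vim, while Twist2 and Foxc2 were at 0.132 ± 0.0239 and 0.134 ± 0.0253 FPKM. Tumours contain stromal cells that express Vim and Fn1, and bulk values do not separate cell types.

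Milk and secretory genes were detected in all 3 tumours, with 9 of 12 measured members above 1 FPKM. After Csn3 and Lcn2, the milk protein gene Lalba was at 278 ± 188 FPKM and ranged from 72.2 FPKM in tumour 1 to 440.1 FPKM in tumour 3 as deposited, and from 95.1 to 367 FPKM with GC and length trends removed. The late-lactation gene Wap was not separated from 1 FPKM (0.0946, 2.36 and 0.53 FPKM) and Csn1s2b was below it. The luminal list mean minus the milk list mean was -0.41 ± 0.15 log2 units, and 0.65 with medians over members. With GC and length trends removed it was -0.40 ± 0.39, negative in 2 of 3 tumours.

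Cell division and glycolysis genes were high throughout. Of 23 measured proliferation genes 22 were above 1 FPKM and none below, led by the cyclin gene Ccnd1 at 158 ± 47.9 FPKM, Pcna at 75.2 ± 3.12 FPKM and Birc5 at 41.3 ± 3.94 FPKM. The lowest were E2f1 (2.03 ± 0.674 FPKM) and Foxm1 (2.13 ± 0.274 FPKM). All 12 hypoxia and glycolysis genes were above 1 FPKM, with Ldha at 412 ± 169 FPKM, Pgk1 at 313 ± 63.7 FPKM and Egln3 at 137 ± 25.1 FPKM, and the lowest was Car9 at 1.88 ± 0.295 FPKM. Of 19 measured cancer genes 18 were above 1 FPKM, with Akt1 at 25.1 ± 6.94 FPKM and Nf1 at 19.2 ± 3.01 FPKM. Brca2 (1.23 ± 0.861 FPKM) was not separated from that level and Cdkn2a was at 1.93 ± 0.836 FPKM. Immediate early and stress genes were above 1 FPKM in 8 of 10 cases, with Hspa1b at 23.4 ± 2.40 FPKM and Junb at 14.7 ± 4.26 FPKM.

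**Figure D2:**
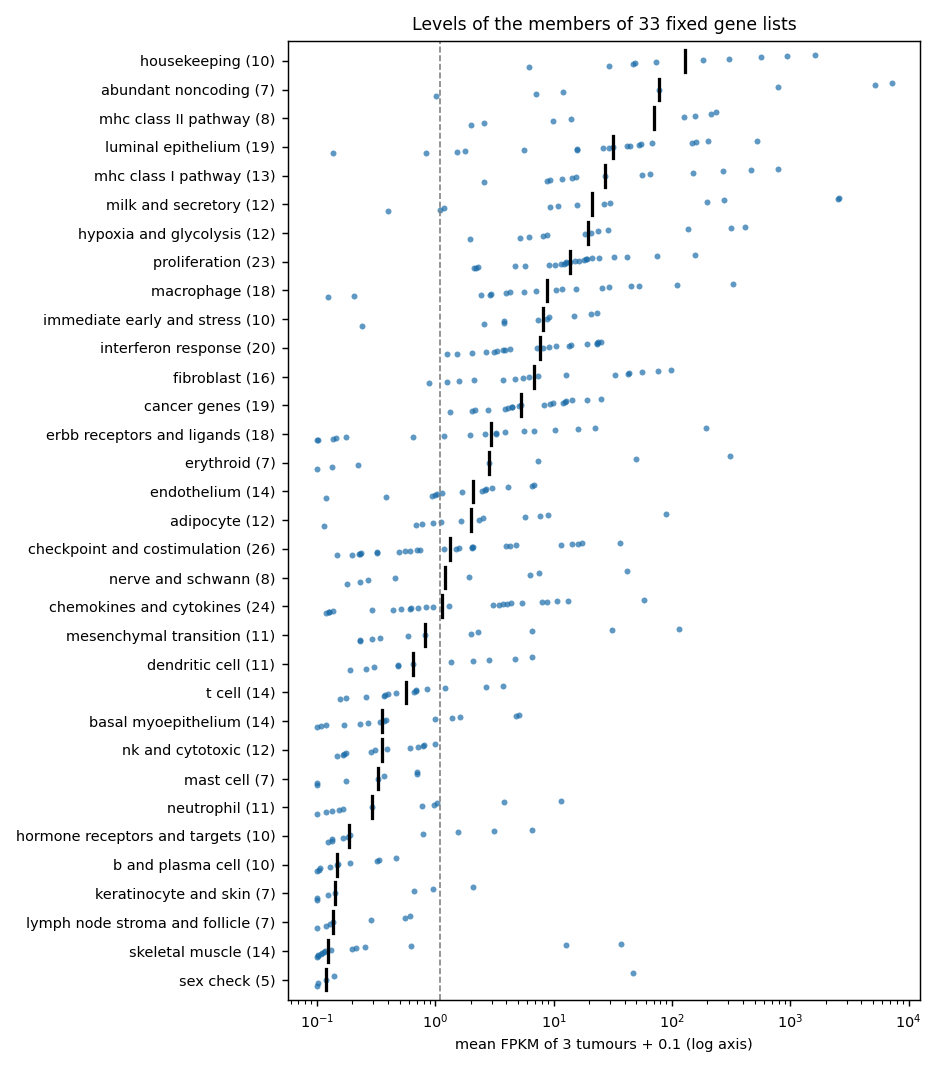
Mean FPKM + 0.1 of each measured member of the 33 fixed lists on a log axis, with the number of measured members in brackets. Each point is 1 gene, each black bar is the list median and the dashed line marks 1 FPKM. Housekeeping genes have the highest median, at 129 FPKM, and the B-cell, skeletal muscle and sex-check lists are among 6 with medians under 0.1 FPKM.

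Among immune cell lists, macrophage genes were the most abundant. Lyz2, the macrophage lysozyme, reached 326 ± 243 FPKM, the complement gene C1qa 111 ± 60.4 FPKM and Cd14 52.4 ± 15.9 FPKM, and 16 of 18 measured members were above 1 FPKM. Arg1, which encodes arginase and marks alternatively activated macrophages, was at 25.4 ± 3.91 FPKM and the scavenger receptor gene Mrc1 at 6.98 ± 2.70 FPKM, whereas the inducible nitric oxide synthase gene Nos2 was at 0.104 ± 0.0490 FPKM. Arg1 exceeded Nos2 by 6.98 ± 0.19 log2 units and Mrc1 exceeded it by 5.07 ± 0.74 (5.08 ± 1.17 with GC and length trends removed). Dendritic cell genes had 4 of 11 members above 1 FPKM, among them Itgax at 6.51 ± 2.67 FPKM, which macrophages also express. Xcr1 and Clec9a, which mark cross-presenting dendritic cells, were at 0.0918 ± 0.0942 and 0.160 ± 0.122 FPKM. Of 11 measured neutrophil genes S100a8 and S100a9 were above 1 FPKM, at 11.5 ± 9.23 and 3.70 ± 2.69 FPKM, and Mpo was at 0.0196 ± 0.0232 FPKM. With GC and length trends removed only 1 neutrophil gene was above 1 FPKM. The macrophage list mean exceeded the neutrophil mean by 4.19 ± 0.19 log2 units. Of 7 mast cell genes none was above that level.

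Lymphocyte genes were low. Of 14 measured T-cell genes 2 were above 1 FPKM and 7 below, and 1 was above when adjusted over the list alone. The count above was also 1 with pseudocount 1, with median-of-ratios scaling, without tumour 2 or 3 and with GC and length trends removed. Cd247 was at 3.68 ± 0.773 FPKM and Cd3g at 2.62 ± 2.02 FPKM. The coreceptor gene Cd4 was at 0.755 ± 0.375 FPKM and not separated from 1 FPKM. Cd8a was below it at 0.279 ± 0.168 FPKM, as was Foxp3, the regulatory T-cell factor, at 0.301 ± 0.297 FPKM. Cd8a minus Cd4 was -1.21 ± 0.52 log2 units, negative in 3 of 3 tumours. Foxp3 minus Cd8a was -0.03 ± 0.89, and 0.47 without tumour 2. None of 12 NK and cytotoxic genes was above 1 FPKM and 8 were below, or 7 when adjusted over the list alone. Gzmb was at 0.890 ± 0.612 FPKM and Prf1 at 0.0467 ± 0.0485 FPKM. All 9 B-cell and plasma-cell genes listed above 0 were below 1 FPKM, with Cd79b highest at 0.364 ± 0.286 FPKM. The macrophage list mean exceeded the T-cell mean by 3.93 ± 0.29 log2 units and the T-cell mean exceeded the B-cell mean by 1.61 ± 0.54. The T-cell mean minus the NK mean was 0.59 ± 0.80, positive in 2 of 3 tumours. Follicle and lymph node genes were all below 1 FPKM where listed above 0.

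Of 26 measured checkpoint and costimulation genes 9 were above 1 FPKM and 10 below. The highest was 4632428N05Rik, the older symbol of the checkpoint gene Vsir, at 36.4 ± 13.1 FPKM (mm9 chromosome 10, 59809599 to 59835432). Next came Sirpa at 17.3 ± 6.31 FPKM and Lgals9 at 15.9 ± 2.01 FPKM. Cd274, which encodes the ligand PD-L1, was not separated from 1 FPKM at 0.648 ± 0.217 FPKM (limma adjusted p = 0.089). Its receptor gene Pdcd1 (0.396 ± 0.182 FPKM), the second ligand gene Pdcd1lg2 (0.128 ± 0.138 FPKM) and Ctla4 (0.0985 ± 0.153 FPKM) were below that level. Cd276, another member of the B7 family, was above it at 3.88 ± 0.523 FPKM and exceeded Cd274 by 2.44 ± 0.34 log2 units (2.43 ± 0.81 with GC and length trends removed). Cd274 exceeded Pdcd1lg2 by 1.84 ± 0.42, while Cd274 minus Pdcd1 was 0.63 ± 0.65, positive in 2 of 3 tumours.

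Antigen presentation genes were high for both classes. All 13 measured class I pathway genes were above 1 FPKM, with B2m at 787 ± 133 FPKM, Calr at 469.9 ± 156 FPKM and H2-D1 at 271 ± 152 FPKM, and the lowest was the regulator Nlrc5 at 2.49 ± 1.14 FPKM. With GC and length trends removed B2m was at 448, 824 and 1271 FPKM in tumours 1, 2 and 3. Of 8 class II pathway genes 7 were above 1 FPKM, with Ctss at 237 ± 85.6 FPKM, Cd74 at 214 ± 124 FPKM and H2-Aa at 157 ± 87.7 FPKM. H2-Eb1 was not separated from that level at 1.89 ± 1.15 FPKM. The class I list mean exceeded the class II mean by 0.51 ± 0.51 log2 units, and the difference was -0.48 with medians over members. MHC genes belong to families of similar sequence, so their single values are uncertain. Interferon response genes were above 1 FPKM in 17 of 20 cases, with Irf7 at 25.1 ± 8.01 FPKM and Gbp2 at 23.6 ± 5.43 FPKM. Of 24 measured chemokine and cytokine genes 11 were above 1 FPKM and 8 below. Ccl8 led at 58.6 ± 58.1 FPKM, followed by Cxcl12 at 13.1 ± 2.99 FPKM and Cxcl16 at 10.5 ± 4.46 FPKM, and Il6 was at 0.0256 ± 0.0444 FPKM.

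**Figure D3:**
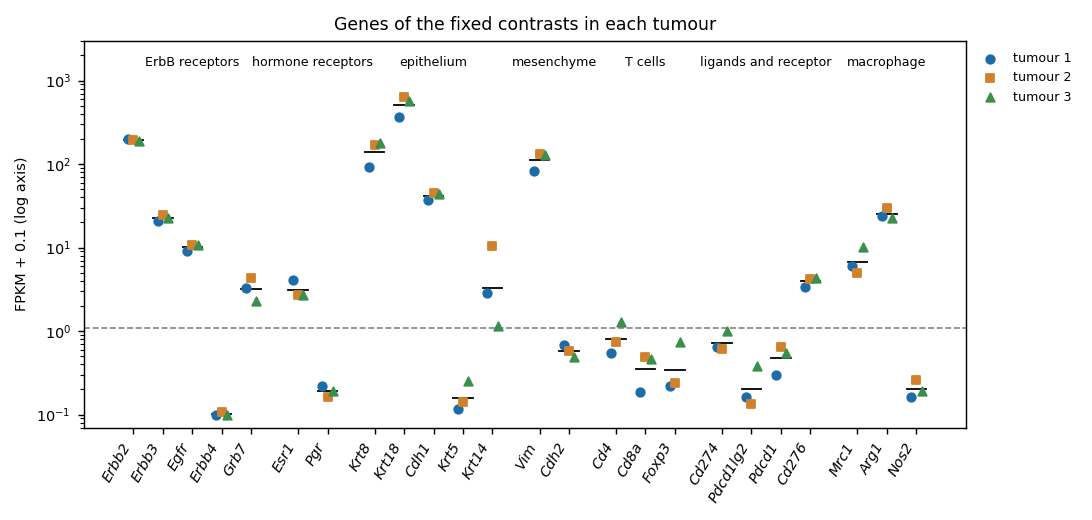
FPKM + 0.1 on a log axis for the genes of the fixed contrasts in each tumour. Symbols mark tumours 1, 2 and 3, the black bar is the geometric mean of the 3 plotted values and the dashed line marks 1 FPKM. Values are as deposited, with Erbb2 at 189.7 to 199.9 FPKM (156 to 260.8 FPKM with GC and length trends removed) and Krt14 at 1.07 to 10.4 FPKM.

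Stromal genes were present at moderate levels. Fibroblast genes were above 1 FPKM in 13 of 16 cases, with the collagen genes Col3a1 and Col1a2 at 98.9 ± 35.6 and 75.7 ± 23.9 FPKM and Postn at 55.6 ± 31.0 FPKM. Endothelial genes were above it in 7 of 14 cases, with Plvap at 6.69 ± 2.08 FPKM and Pecam1 at 6.50 ± 1.41 FPKM, while the lymphatic factor Prox1 was at 0.0204 ± 0.0142 FPKM. The fibroblast list mean exceeded the endothelial mean by 2.56 ± 0.13 log2 units. Adipocyte genes were above 1 FPKM in 5 of 12 cases (2 without tumour 1) and varied strongly, the fatty acid binding protein gene Fabp4 being at 55.7, 41.6 and 173 FPKM in tumours 1, 2 and 3 as deposited and at 35.7, 44.99 and 245 FPKM with GC and length trends removed. Skeletal muscle genes were mostly absent from the listed signal, with 11 of 14 below 1 FPKM and Myh2 at 0.00195 ± 0.000771 FPKM, but Acta1 (36.9 ± 8.21 FPKM) and Mb (12.6 ± 1.71 FPKM) were above it. The adipocyte list mean minus the muscle mean was 2.62 ± 0.92 log2 units, and -1.46 when members under 0.5 FPKM were left out, which leaves 3 muscle genes. Of 7 measured keratinocyte and skin genes only Sbsn was above 1 FPKM, and none without tumour 2 or without tumour 3. In the nerve list Sox10, a factor of neural crest and of some mammary epithelial cells, was at 41.7 ± 4.41 FPKM, and 4 of 8 genes of the list were above 1 FPKM and 4 below. Among 7 erythroid genes Hba-a1 was at 308 ± 30.3 FPKM, but Hba-a2 and Hbb-b1 have close copies in the genome and were listed near 0 in at least 1 tumour, so globin values per symbol are uncertain.

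Xist, the transcript of the inactive X chromosome, was at 47.3 ± 0.762 FPKM as deposited (27.8, 57.3 and 66.8 FPKM with GC and length trends removed), and the Y-linked genes Uty, Ddx3y and Kdm5d were all under 0.05 FPKM on average with Eif2s3y listed at 0, in mice labelled female. All 10 housekeeping genes were above 1 FPKM, with Eef1a1 at 1605 ± 290.0 FPKM, Actb at 936 ± 315 FPKM and Tbp at 6.13 ± 0.6996 FPKM. Of 7 measured abundant noncoding RNAs 6 were above it, Malat1 being at 793 ± 299.9 FPKM. Adjusted over the list alone, the counts above and below 1 FPKM equalled those over all genes in every list but the T-cell and NK lists. Of the 33 lists 20 had a median above 1 FPKM. Of the 27 fixed contrasts 24 had the same sign in all 3 tumours, and 23 with GC and length trends removed. With 3 tumours the exact two-sided sign-flip test cannot give p below 0.25, which is 0.28 after adjustment over the 27 contrasts. No contrast can therefore pass 0.05 by this test, and sizes and SDs are given instead. The SDs are those of deposited values, and with the trends removed 17 of 27 were larger, 7 of them by over 1.5 times. Folds are on the log2(FPKM + 0.1) scale and understate differences to genes near 0.

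The 3 tumours correlated across all genes, with Pearson r of log2(FPKM + 1) of 0.955 between tumours 1 and 2, 0.929 between 1 and 3 and 0.962 between 2 and 3. Genes are not independent replicates, so no p-value is given. The differences between tumours followed base composition in part. With the GC and length trends removed, the SD over genes of the log2 ratio fell from 0.97 to 0.65 between tumours 1 and 3. Between tumours 2 and 3 it fell from 0.52 to 0.46. Across 10837 genes with a mean of at least 1 FPKM, the log2 ratio of tumour 1 to tumour 3 had a Spearman rho of -0.70 with the GC content of the transcript, the ratio of tumour 1 to tumour 2 had -0.64 and that of tumour 2 to tumour 3 had -0.49. Genes in the lowest GC quintile were 2.20-fold higher in tumour 1 than in tumour 3 by median, and those in the highest quintile 1.74-fold higher in tumour 3. For this reason the list shifts and single genes below are given as deposited and after removal of the GC and length trends, a correction chosen after seeing the data.

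**Figure D4:**
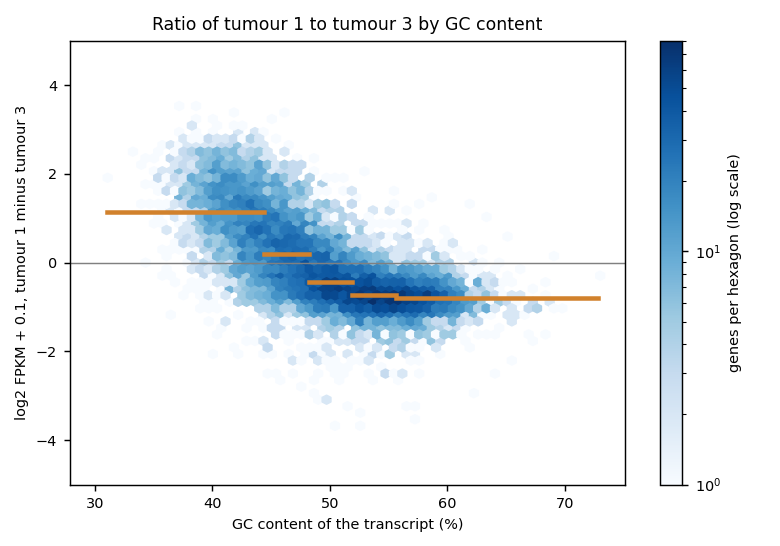
Log2 ratio of tumour 1 to tumour 3 (FPKM + 0.1) against the GC content of the transcript in percent, for genes with a mean of at least 1 FPKM and a locus of at least 300 bp. Shading counts genes per hexagon on a log scale and orange lines are the medians of GC quintiles, which fall from 1.14 to -0.80.

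Many genes differed between single tumours by more than counting error. Of 11193 genes with a mean of at least 1 FPKM, 3597 passed Cochran's Q test with a Benjamini-Hochberg adjusted p under 0.05 and a ratio of at least 2 between the highest and lowest tumour, and 613 reached a ratio of 4. The Q test alone passed 10128 of the 11193, so the required ratio did most of the selection. The count was 636 without tumour 1 and 1561 without tumour 3. After removal of the GC and length trends it was 1667 of 11004, of which 1077 were shared with the deposited values. The test compares 3 libraries, not conditions, and its errors cover counting only. Retnla, a gene of alternatively activated macrophages and adipose tissue, was at 14.3, 2.32 and 79.8 FPKM in tumours 1, 2 and 3, and at 15.2, 2.16 and 81.2 FPKM after correction. The epithelial keratin gene Krt19 was highest in tumour 3 (0.418, 0.0184 and 3.04 FPKM after correction). The retinoid-binding protein gene Crabp1 was lowest in tumour 1, at 0.379 FPKM against 2.89 and 4.54 FPKM (0.603, 2.60 and 3.39 FPKM after correction). The zinc finger gene Zfp62 (9.76, 1.48 and 0.774 FPKM) and the cadherin gene Cdh19 (7.72, 0.619 and 1.33 FPKM), with transcripts of 38.8% and 37.4% GC, were highest in tumour 1. After correction Zfp62 was at 5.11, 1.72 and 1.30 FPKM and Cdh19 at 3.67, 0.767 and 2.28 FPKM. Nlrp10 (1.27, 2.49 and 0.222 FPKM) and Tmigd1 (1.26, 1.67 and 0.109 FPKM) were lowest in tumour 3, with 0.321 and 0.181 FPKM there after correction. Cck was lowest in tumour 2 (1.13, 0.0731 and 3.02 FPKM, and 1.698, 0.0564 and 2.25 FPKM after correction). Crabp1, Zfp62, Cdh19, Nlrp10 and Tmigd1 were no longer among the 5 largest rises or falls of any tumour after correction. The other largest differences were at the small RNA loci Snord83b, Mir1894, Mir505, Snord58b, Mir721 and Snora69, at the globin gene Hba-a2, and at Gm12191, Moap1, Gm12238, 2200001I15Rik and 3110070M22Rik, several of which were listed near 0 in at least 1 tumour.

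Macrophage, class II and neutrophil genes were lowest in tumour 1 and highest in tumour 3. Against the other tumours together, all 8 class II genes were higher in tumour 3, with a median shift of 1.06 log2 units as deposited and 0.84 after correction, and all 8 were lower in tumour 1 (-1.12 and -0.89). Against tumours 1 and 2 taken singly, the class II median of tumour 3 was higher by 1.44 and 0.71 as deposited and by 1.13 and 0.52 after correction. Cd74 was at 97.8, 200.2 and 344 FPKM in tumours 1, 2 and 3, and at 141, 182 and 261 FPKM after correction. The median shift of 16 macrophage genes in tumour 3 was 0.65 as deposited and 0.60 after correction, with 12 genes higher. The 5 neutrophil genes counted were shifted by 1.45 (1.90 after correction) in tumour 3 and by -1.59 (-2.02) in tumour 1, and 6 dendritic cell genes by 0.65 (0.50) in tumour 3. The dendritic cell shift rested mainly on tumour 1, since against tumour 2 alone it was 0.34 in both forms, inside the random range. Chemokine and cytokine genes were higher in tumour 3 in 15 of 17 cases (median 1.06, and 1.39 after correction), Ccl8 being at 18.97, 31.5 and 125 FPKM, and at 21.3, 29.1 and 122 FPKM after correction. T-cell genes were shifted by 1.34 (1.04 after correction) in tumour 3 and by -1.28 (-1.12) in tumour 1, at low levels. The 14 measured T-cell genes had deposited medians of 0.11, 0.39 and 0.73 FPKM in tumours 1, 2 and 3. Against tumour 1 alone 6 of the 7 counted were higher in tumour 3 as deposited, Cd247 being lower (-0.82), and all 7 after correction. The tumour 1 shift rested mainly on tumour 3, since tumour 2 minus tumour 1 was 0.59 as deposited and 0.35 after correction, the latter inside the random range. Class I genes were higher in tumour 3 by 0.89 (0.59). Apart from the comparisons of single pairs, each of these median shifts lay outside the central 95% of random lists before and after correction. The 10000 random lists were matched on size and mean expression.

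Adipocyte genes set tumour 3 apart. The tumours grew in mammary fat pads, and the share of fat-pad tissue in each sample was not measured. Against the mean of the other tumours, 11 of 11 adipocyte genes were higher in tumour 3 as deposited and 10 of 11 after correction, with median shifts of 1.64 and 1.74. The matching shift of tumour 2 (-1.37, and -1.46 after correction) rested mainly on tumour 3, since against tumour 1 alone it was -0.34 and -0.39, both inside the random range. Interferon response genes were lower in tumour 2 than the mean of the other tumours in 20 of 20 cases, with a median shift of -0.73 (-0.79 after correction), and the list was higher in tumour 1 by 0.65 (0.64). The tumour 1 shift rested mainly on tumour 2, since tumour 3 minus tumour 1 was -0.26 as deposited, inside the random range. After correction it was -0.34, outside that range, so tumour 1 was then higher than each other tumour. Against tumour 3 alone 16 of 20 were lower in tumour 2 as deposited. Luminal genes were shifted in tumour 3 by -0.19 as deposited, inside the random range, and by -0.29 after correction, outside it. Fibroblast genes were higher in tumour 2 by 0.43 in both, with 10 of 16 higher, and hypoxia and glycolysis genes by 0.32 (0.33). As deposited, the single pairs of hypoxia and glycolysis genes were inside the random range (tumour 2 minus tumour 1 0.33, tumour 3 minus tumour 2 -0.21). After correction both pairs were outside it (0.31 and -0.30). Beside adipocyte and interferon genes, NK and cytotoxic, class I and proliferation genes were below the random range in tumour 2 in both forms. For NK and cytotoxic genes the shift was -1.08 in 5 genes as deposited and -0.97 in 4 genes after correction. Class I genes were at -0.39 and -0.49, and proliferation genes at -0.13 and -0.16. The class I shift rested on tumour 3, since tumour 2 minus tumour 1 was 0.02 as deposited and -0.11 after correction, both inside the random range. For proliferation genes tumour 2 minus tumour 1 was -0.00097 and -0.07, also inside. After correction their tumour 3 minus tumour 2 value was 0.12, inside that range too. Cancer genes, by contrast, were shifted by -0.84 in tumour 3 as deposited and by -0.09 after correction, which is inside the random range. ErbB receptors and ligands stayed inside the random range in all 3 tumours, with and without the correction. Over 87 list and tumour combinations 29 medians lay outside the central 95% as deposited and 26 after correction, where 5% of them is 4.35, and 22 did so in both forms and with the same sign. The random lists were drawn from unrelated genes, while members of a fixed list may vary together. The 4.35 is therefore not the number expected from ordinary variation between tumours. The deposited count was 17 with means over members and 18 without tumour 2. With 2 tumours left each of the 29 lists gives 1 comparison and its mirror image, so the 18 is not out of 87. In the simulation 10% of 40 unchanged lists lay outside before correction and 5% after, but these were lists of randomly drawn genes. They cannot tell how a GC trend moves lists of related genes. The 3 shifts of a list are not independent because each tumour serves in the comparison of the others.

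**Figure D5:**
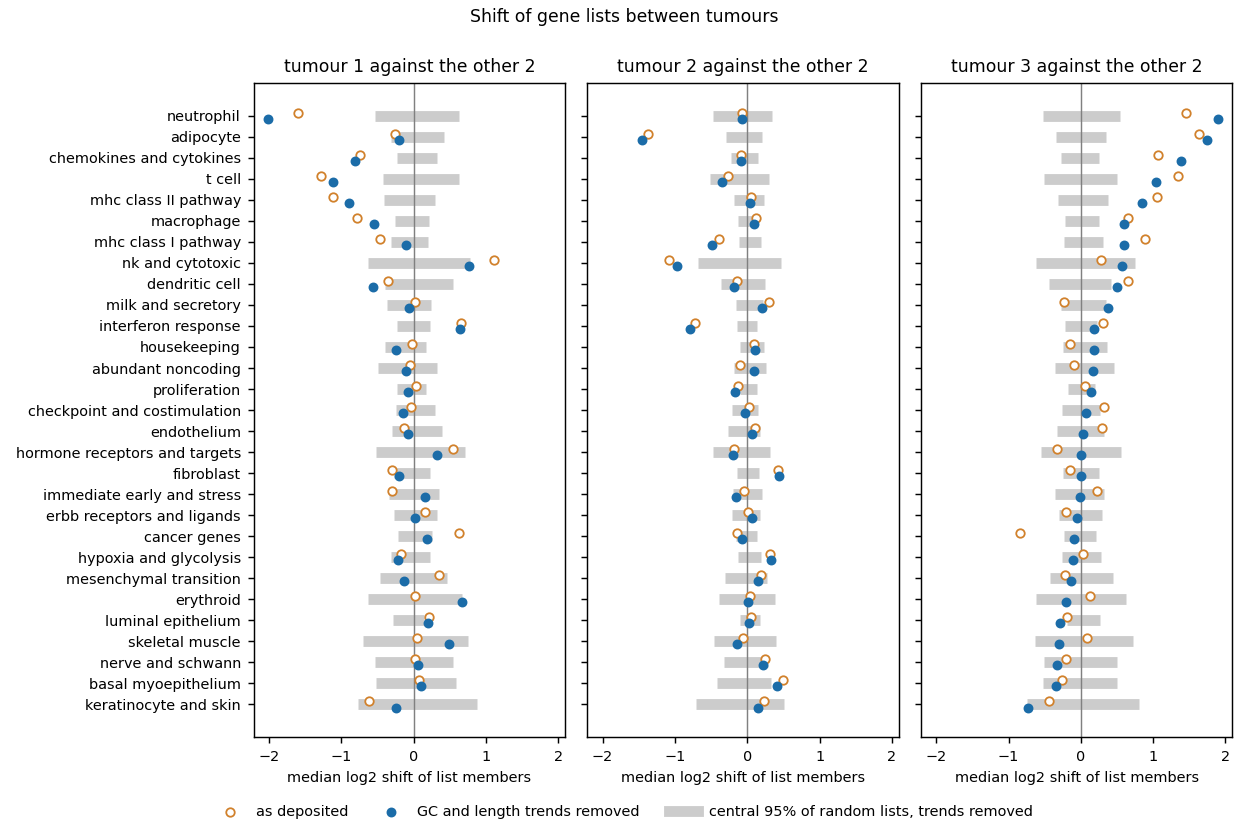
Median log2 shift of each list in 1 tumour against the other 2. Open circles are deposited values, filled circles are values with GC and length trends removed and grey bars are the central 95% of random lists for the corrected values. Class II genes in tumour 3 lie at 1.06 and 0.84, and cancer genes in tumour 3 move from -0.84 to -0.09.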

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

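The Erbb2 neighbours and the weighing of base composition, immune content and gene amplification under the other observations were chosen only after the results were seen. No test was run on the genes of this part. Their status was not OK in at least 1 tumour, which left them out of the tests. Listed values were nevertheless above the limit of 3 fragments at the median locus in all 3 tumours for 41 of 45 gene entries with a FAIL or HIDATA status and for 38 of 236 with a LOWDATA status. The highest were Acsl4, which encodes a fatty acid ligase, with a mean of 131 FPKM (228, 96.2 and 69.5 FPKM in tumours 1, 2 and 3) and Spna2, an older symbol of a spectrin gene, with 124 FPKM. They were followed by the thioredoxin-binding gene Txnip with 96.2 FPKM, the chaperone gene Canx with 91.0 FPKM and the catenin gene Ctnnd1 with 72.5 FPKM. Of these 5 genes Acsl4 and Spna2 had a FAIL status in all 3 tumours and the others in 1 tumour. Celf2, which is not among those above the limit in all 3 tumours, was listed at 8.71 FPKM with status OK in tumour 1 and at 0 with status HIDATA in the others, which shows that a 0 under such a status is not a measured absence.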

How the results depend on the processing

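The removal of the GC and length trends and the omission of loci under 300 bp were chosen only after results were seen. The count above 1 FPKM ranged from 7707 to 11636 over the alternatives, and from 8833 to 9880 when 1 tumour was left out. The count below was 2228 with a mean of at least 0.1 FPKM, where fewer low genes are tested. Lists with a median above 1 FPKM numbered 18 to 21. Of 2918 alternative values for the levels of 212 named genes, 2740 kept side and call, 81 became weaker, 78 stronger and 19 reversed. Rescaling to a fixed total, which raises every gene, gave 0.78 for Cd274, 0.92 for Cd4, 0.41 for Cdh2, 1.14 for Csf3r, 0.29 for Cxcl13, 0.61 for Krt10, 1.23 for Meg3, 0.54 for Mylpf, 0.0488 for Pdcd1, 1.02 for Pi16 and 0.95 for Spdef, in log2 units from the level. A level of 2 FPKM gave -0.10 for Car9, -0.13 for Cdkn2a, -0.0324 for E2f1, -0.80 for Fbln1 and -0.0724 for Sbsn, and a level of 0.5 FPKM gave 0.13 for Krt10 and 0.0646 for Mylpf. Nlrp10 ranged from -0.73 to 0.78 when 1 tumour was left out. Of 181 alternative contrast values 176 kept their sign. Those that did not were luminal minus milk (0.65) and class I minus class II (-0.48) with medians over members, adipocyte minus muscle without members under 0.5 FPKM (-1.46), and Foxp3 minus Cd8a with pseudocount 1 (0.00998) and on leaving out 1 tumour (-0.39 to 0.47). T cell minus B cell could not be given without members under 0.5 FPKM, as no B-cell gene was left. Differing genes numbered 1823 with a mean of at least 5 FPKM, 613 at 4-fold, 1667 after removal of the trends and 636 to 3285 when 1 tumour was left out. List shifts outside the random range numbered 17 with means over members and 18 to 24 when 1 tumour was left out. With 1 tumour left out each of the 29 lists gives 1 comparison and its mirror image. The counts of 18 to 24 are thus not out of 87 combinations. Correlations were 0.889 (tumours 1 and 2), 0.826 (1 and 3) and 0.908 (2 and 3) for genes with a mean of at least 1 FPKM. Tumours 1 and 3 had 0.946 with trends removed and 0.947 without loci under 300 bp, and tumours 2 and 3 had 0.985 without such loci. Where no reason is given the cause was not tested. A pseudocount in place of intervals was not run for differing genes, because intervals were given. No paired analysis was possible because there is 1 group. At the median locus 0.04 FPKM corresponds to about 3 fragments, and the number differs between genes.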

Other observations

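The genes of the first 2 paragraphs other than Sox10 and Krt14, and the trend, immune and locus tests after them, were chosen only after values were seen. Aqp5, a water channel of secretory glands, was at 588 ± 168 FPKM (SD, n = 3), the alveolar regulator Elf5 at 55.3 ± 3.49 FPKM and Sox10 at 41.7 ± 4.41 FPKM. The chemokine gene Cxcl14 was at 5.42, 55.4 and 30.9 FPKM in tumours 1, 2 and 3, and at 7.701, 50.4 and 24.002 FPKM with GC and length trends removed. The collagenase gene Mmp13 (0.838, 5.87 and 0.487 FPKM) and the surface protein gene Ly6d (1.25, 16.1 and 3.90 FPKM) were highest in tumour 2, the same tumour in which Krt14 was highest. With the trends removed Mmp13 was at 0.5305, 6.13 and 0.734 FPKM and Ly6d at 1.84, 14.5 and 2.97 FPKM.

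The chemokine gene Ccl4 was at 3.26 FPKM in tumour 3 against 0.297 and 0.0772 FPKM in tumours 1 and 2 (2.88, 0.389 and 0.0623 FPKM with GC and length trends removed). Adipoq, the adipocyte hormone gene, was at 3.20, 1.51 and 12.4 FPKM in tumours 1, 2 and 3 (3.499, 1.41 and 12.1 FPKM with the trends removed). The interferon-induced gene Ifit1 fell from 16.9 FPKM in tumour 1 to 6.20 and 3.91 FPKM in the others, and from 12.8 to 6.20 and 5.18 FPKM with the trends removed. Zfp260, a zinc finger gene with a transcript of 41.7% GC, was at 18.8, 5.00 and 1.70 FPKM, and at 12.1, 5.304 and 2.53 FPKM with the trends removed.

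The fall of the ratio of tumour 1 to tumour 3 with GC content was set against transcript length, low depth and base-composition bias of the libraries. Within quartiles of transcript length the weakest Spearman rho was -0.469, so length alone does not account for it. Among 1948 genes with at least 1000 implied fragments in each tumour it was -0.701, which leaves low depth out. Within 15 fixed lists, each of related genes, rho was negative in 14 (93.3%), as a bias of the libraries predicts. The exception was the chemokines with 0.49, and adipocyte genes had only -0.05. Any cause that acts on genes by their GC content predicts the same, so this count does not single out a bias of the libraries. A biological difference that follows GC content was not separated from such a bias.

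The higher macrophage and class II genes in tumour 3 than in tumour 1 were set against the GC trend and a lower share of tumour cells alone. After correction the median of 24 members was 1.01 log2 units, at percentile 100 of random lists, so the trend does not account for it. A lower share of tumour cells alone predicted an equal rise of fibroblast and endothelial genes, but 28 of these had a median of 0.14, a difference of 0.87 (two-sided permutation p = 7.0e-05 over genes, which are not independent). Macrophage and class II genes were chosen after their higher values in tumour 3 had been seen, so this p-value partly restates that choice. It compares 1 library with 1 other and does not measure the spread between animals. Corrected luminal genes were lower in tumour 3 than in tumour 1 (-0.26, 15 of 18 lower). Adipocyte genes, which were not in the comparison set, were higher (1.44, 10 of 11 higher). A lower share of tumour cells beside another change therefore stays open. Neutrophil, dendritic cell and T-cell genes were also higher (2.73, 0.77 and 1.70 after correction), so the values may reflect more immune cells of any of these types or higher expression in each, which bulk RNA does not separate.

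Amplification of the endogenous Erbb2 locus predicted raised neighbours. The median neighbour within 100 kb lay at FPKM percentile 42.0, and 8 of 9 were under 10% of Erbb2. The median does not describe every neighbour, since 1810046J19Rik lay at percentile 95.6 and Stard3 at 85.2. The others lay at 54.9 (Grb7) or lower. 1810046J19Rik, at 25.6% of Erbb2, overlaps it by 9 bp and may hold fragments of Erbb2, but whether so short an overlap accounts for its value was not tested. DNA copy number was not analysed here, and expression alone leaves amplification open, since neighbours need not rise with copy number. The Erbb2 transgene known from the NDL model is another possible source of the high Erbb2 value. It was not tested, because FPKM per symbol does not separate it from the endogenous gene.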
